A study of Mus musculus with 12 samples.

How the data were processed

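RNA was measured in 12 samples of mouse XEN cells that carry an Afp::GFP transgene and were grown in N2B27 medium, per the labels: 3 untreated, 3 given BMP4, and 3 each of the GFP positive and GFP negative cells sorted after BMP4. Total RNA was isolated with RNeasy columns, labelled as biotin cRNA with a MessageAmp kit and hybridized to Illumina MouseWG-6 V2.0 arrays. The deposited scanner table, exported from BeadStudio 3.4.0 without normalization, holds for each of 45281 probes the mean bead signal as an intensity and a detection value. The deposited detection value is a fraction, 1 minus the detection p. The deposited processed table holds log2 values of 20178 probes, and the processing notes name lumi. Its transform, normalization, probe filter and the version of lumi are not given in the sources used here. Against log2 signal its slope was 0.995 in the 2000 brightest probes and 0.416 in the dimmer ones, and its column medians differed by at most 0.00033. Its probe identifiers could not be linked to gene names, so it was used only to count probes. The dose and duration of BMP4, the slides and the relation between replicates of a group are not given in the sources used here.

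Signals were background corrected from the detection p, since no control probes were used, offset by 16, quantile normalized and put on the log2 scale with limma 3.58.1 in R 4.3.3. Probes with a detection p under 0.01 on at least 3 arrays were kept, 15448 in all, and 29833 were dropped. File symbols were brought to current names where equal (13430) or matched by 1 synonym (8112), and 9948 were kept as given. The brightest kept probe stood for its gene, which gave 10597 genes, 3424 of them with more than 1 kept probe. Kept probes of 1 gene were called in both directions for 63, 1 and 338 genes in the 3 comparisons. No array was identical to another. Median signal was 53.4 to 60.9 on unsorted and 22.6 to 32.4 on sorted arrays, above a lowest signal of 24.5 to 27.4 and 3.3 to 6.8.

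A linear model with 4 group means was fitted to the 12 arrays in limma with moderated standard errors (8 residual degrees of freedom, 5.08 prior degrees of freedom, median residual SD 0.116). The comparisons were BMP4 against untreated, GFP positive against GFP negative, GFP negative against untreated, and the difference between the first 2. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 in limma. Where no array of a group detected a gene, values of that group were raised to the lowest normalized value of any detected probe on each array before the fold was taken, and the fold is given as at least that large. The same bound, chosen after the data were seen, is given where 1 or 2 arrays of a group detected a gene and its mean lay under that level. Where neither group was detected no fold is given.

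The 20 gene lists covered visceral, anterior visceral, parietal and primitive endoderm markers, apolipoproteins, serum proteins, BMP targets and components, epithelial, mesenchymal and basement membrane genes, cholesterol synthesis, endocytosis, cell cycle, stress, p53, glycolysis, interferon, imprinted, and WNT and FGF genes. The 6 cell type lists covered pluripotent, trophoblast, mesoderm, fibroblast, gut endoderm and neural cells. Lists with at least 3 measured genes, 25 of 26, were tested with camera in limma at a preset correlation of 0.01 and with an estimated correlation, and adjusted over lists. The groups, comparisons, lists, thresholds, alternatives and naming rule were chosen before the data were examined, except where stated. Genes are named by that rule: the 12 largest rises and falls in each of the first 2 comparisons and the 6 in the third, among called genes whose arrays did not overlap and which have a gene name, up to 4 members of each list with the largest change, and 25 genes set in advance. Other members of lists, named where 5 or fewer passed, and further called list members were chosen after their values were seen.

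Alternatives were no background correction, an offset of 50, scale normalization, the processed table, no or a stricter detection filter, the mean of the kept probes, only the compared groups in the fit, array weights, a replicate block, adjusted p under 0.01, an absolute log2 change of at least 1, estimated correlation, and leaving out each array in turn. Testing each kept probe on its own, and every alternative for genes called in both main comparisons, were added after the data were seen.

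The model fit and the calling were tested on simulated normalized values with independent noise and 10397 unchanged genes. Background correction, normalization and probe choice were not simulated. Far fewer genes were changed than the 58.9% called for BMP4, so the rates may not hold for the real comparisons. Changes of 0.5, 1 and 2 on the log2 scale were recovered in 80.6%, 98.5% and 100% of planted genes for BMP4, 76.1%, 97.0% and 100% between the fractions, 68.7%, 100% and 100% in the third comparison and 34.3%, 94.0% and 98.5% for the difference, with 11, 9, 12 and 2 unchanged genes called.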

Results

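Expression was measured on 12 arrays of RNA from XEN cells, stem cells of the mouse extraembryonic endoderm, in a line whose green fluorescent protein (GFP) reporter is driven by the alpha-fetoprotein gene Afp. The 4 groups of 3 arrays each were untreated cells, unsorted cells given BMP4, and the GFP positive and GFP negative cells sorted after BMP4. The median signal per array was 53.4 to 60.9 on the 6 arrays of unsorted cells and 22.6 to 32.4 on the 6 arrays of sorted cells. Between 13872 and 14737 of 45281 probes were detected on the unsorted arrays and between 13105 and 13745 on the sorted ones. Arrays of 1 group correlated across the 10597 genes tested with r between 0.994 and 0.997, where genes are not independent replicates. The number of arrays, 3 per group, limits the precision of every value. The labels do not say that the replicates of a group were separate cultures, so each adjusted p measures only the spread between arrays. Group values are mean log2 signal ± SD and differences are log2 ± SE, with n = 3 arrays per group. Positions in the genome are not given, since no build is named in the files.

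The first comparison asked what BMP4 changed in unsorted XEN cells, and whether markers of the visceral endoderm, the absorptive epithelium around the early embryo, were among the genes that moved. Amnionless (Amn, probe 2510743), the membrane partner of the endocytic receptor cubilin, rose from 5.21 ± 0.18 to 11.24 ± 0.13 (SD), at least 54.4-fold (adjusted p = 5.05e-14), with 1 of 3 untreated arrays detecting it. Other visceral endoderm genes rose with it: the endocytic receptor gene Lrp2 by 3.09 ± 0.12, apolipoprotein E (Apoe) by 3.18 ± 0.09, the transcription factor gene Hnf4a by 1.87 ± 0.12 and Indian hedgehog (Ihh) by 1.21 ± 0.09. Genes of the parietal endoderm, the matrix-secreting cells that face the mother, fell: nidogen 1 (Nid1) was lower by a log2 difference of -2.80 ± 0.13 and thrombomodulin (Thbd) by one of -2.72 ± 0.13. The E-cadherin gene Cdh1 rose by 1.98 ± 0.14, and the direct BMP target Id1 by 3.14 ± 0.12.

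BMP4 changed 6244 of 10597 genes, 58.9%, of which 3203 rose and 3041 fell, and 1058 changed at least 2-fold (442 up, 616 down). With scale normalization 2758 rose and 2767 fell, so neither direction held the majority under both. The 3 arrays of each group did not overlap in 61.3% of genes, against the 10% that chance gives. Among the 12 largest rises were also fibulin 1 (Fbln1, probe 2690070), a matrix glycoprotein, troponin C (Tnnc1), the protease inhibitor gene Serpina10, the VEGF receptor gene Flt1 and the interferon-induced membrane protein gene Ifitm1. Tnnc1 rose from 7.26 ± 0.20 to 12.60 ± 0.13 (SD) and Flt1 from 6.93 ± 0.16 to 11.60 ± 0.17. Fbln1, Serpina10, Misp3, Ifitm1 and the cell cycle inhibitor gene Cdkn1c were not detected on any untreated array, and after BMP4 they were at least 27.6-fold, 16.5-fold, 19.2-fold, 13.8-fold and 10.1-fold higher. Such a bound compares the detected group with the lowest signal that counted as detected on the arrays of the other group. The bound is also given where a group was detected on 1 or 2 arrays with a mean under that signal, as for Amn and for Fmo1, at least 19.1-fold higher. Lgals2, Plac8 and Akr1c19 completed the 12, with Akr1c19 up by 4.10 ± 0.07. The 5 kept probes of Fbln1 gave log2 differences from 0.18 to 5.54, the 2 of Flt1 gave 0.98 and 4.66, the 2 of Fmo1 gave 2.17 and 4.41, and the 3 of Ifitm1 ran from 0.80 to 4.66, so the values given hold for the brightest probe.

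The largest fitted fall after BMP4 was in Nupr1 (probe 1240424), a stress-induced regulator of transcription. It went from 12.10 ± 0.11 to 6.55 ± 0.33 (SD), a difference of -5.55 ± 0.17 (adjusted p = 1.09e-11). Genes given only a bound may have fallen by more. Depp1, detected on 1 BMP4 array, was at least 27.0-fold lower. The branched-chain aminotransferase gene Bcat1, the G protein subunit gene Gnai1 and the sphingosine kinase gene Sphk1 were not detected after BMP4 and were at least 16.5-fold, 14.2-fold and 12.4-fold lower. The semaphorin gene Sema6d, the mitochondrial acetyl-CoA synthetase gene Acss1, Spink4, Wipf3 and the chromatin organizer gene Satb1 were also lost from detection, at least 11.2-fold, 7.78-fold, 8.04-fold, 6.27-fold and 5.77-fold lower. Igfbp5, which binds insulin-like growth factors, fell by 3.71 and Mllt3 fell by 3.61. These values hold for the brightest probe: the 3 probes of Bcat1 ran from -4.97 to -0.95 and the 4 of Mllt3 from -3.61 to -1.73.

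Of 24 measured visceral endoderm markers, 21 rose after BMP4 and 3 fell, the same numbers as adjusted over the list alone, and the list was higher as a set (adjusted p = 5.04e-09). With an estimated correlation between genes that call was lost (adjusted p = 0.0594 with an estimated correlation). Apolipoprotein M (Apom) and apolipoprotein A1 (Apoa1) were not detected in untreated cells and were at least 5.19-fold and 5.37-fold higher. The retinol carrier gene Rbp4 was at least 1.56-fold higher on the same terms. The trypsin inhibitor gene Spink1 rose by 3.68 ± 0.10. The 3 members that fell were transthyretin (Ttr), the endocytic adaptor gene Dab2 and Foxa2, by at most 0.34 on the log2 scale. Of 3 measured anterior visceral endoderm markers, Hhex (1.96 ± 0.07) and Fzd5 (1.05 ± 0.09) rose and Dkk1 (-0.48 ± 0.10) fell, as also adjusted over the list alone, and the list did not pass (adjusted p = 0.182). The anterior marker Cer1 was not detected on any array.

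Secreted and lipid transport proteins made by visceral endoderm and liver moved with these markers. Of 9 measured apolipoprotein and lipid transport genes, 6 rose and 3 fell, and the same numbers passed adjusted over the list alone (adjusted p = 0.00855 for the list, adjusted p = 0.0864 with an estimated correlation). Apolipoprotein A2 (Apoa2) was at least 12.7-fold higher, while Fabp3 and Vldlr were among the 3 that fell. Of 12 serum proteins and coagulation factors, 10 rose and 1, Ttr, fell, and 11 rose and 1 fell adjusted over the list alone. The coagulation factor gene F10 counts as risen, but no untreated or BMP4 array detected it, so no fold is given. That list was higher (adjusted p = 4.28e-05, adjusted p = 0.0719 with an estimated correlation), with the transferrin gene Trf up by 1.91 ± 0.13 and prothrombin (F2) and Ambp at least 2.83-fold and 2.25-fold higher.

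Of 19 measured parietal endoderm markers, 4 rose and 13 fell after BMP4, the same numbers as adjusted over the list alone. The list was lower (adjusted p = 0.00855, adjusted p = 0.163 with an estimated correlation). The connective tissue growth factor gene Ccn2 fell by 2.36, the laminin genes Lama1 by 1.24 and Lamc1 by 1.27, and vimentin (Vim) by 0.58. The 4 that rose were Cited1 (3.57 ± 0.08), Krt19, the transcriptional repressor gene Snai1 (0.68 ± 0.11) and Pth1r. Basement membrane genes, which share laminin, collagen IV and nidogen genes with that list, went the same way: 15 of 22 fell and 4 rose, as also adjusted over the list alone (adjusted p = 0.0224 for the list, adjusted p = 0.268 with an estimated correlation). The 4 that rose were Fbln1, agrin (Agrn, 1.65 ± 0.09), Lamb3 and Lama5. Lamb3 was detected on 1 BMP4 array, with a mean of 5.21 under the lowest detected signal of 5.57, so no fold is given.

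Of 11 genes of primitive endoderm identity, 3 rose and 5 fell, or 3 and 6 adjusted over the list alone, and the list did not pass (adjusted p = 0.195). Among the transcription factors, Gata6 fell by 0.77, Sox7 by 0.87 and Foxq1 by 1.29, although 1 of the 3 kept probes of Sox7 gave 0.01. Lamb1 fell by 1.18, and Sall4 and Pdgfra were among the 3 that rose.

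Several genes that mark these endoderm states lay near the threshold, and 1 array decided their calls. Ttr was 12.33 ± 0.12 after BMP4 and 12.55 ± 0.04 (SD) untreated (adjusted p = 0.0299), and the call was lost without untreated replicate 2 (adjusted p = 0.0881), untreated replicate 3 (adjusted p = 0.0610) or BMP4 replicate 1 (adjusted p = 0.123), in a range of 0.0184 to 0.123 over all alternatives. Dab2 differed by -0.22 ± 0.07 (adjusted p = 0.0165), lost without untreated replicate 2 (adjusted p = 0.0650) or BMP4 replicate 3 (adjusted p = 0.0569), in a range of 0.0114 to 0.181. Foxa2 differed by -0.34 ± 0.11 (adjusted p = 0.0188), lost without untreated replicate 1 (adjusted p = 0.0834, difference -0.19) or BMP4 replicate 2 (adjusted p = 0.0634), in a range of 0.00709 to 0.0834. The matrix gene Sparc differed by -0.30 ± 0.09 (adjusted p = 0.0118), lost without untreated replicate 3 (adjusted p = 0.0521), in a range of 2.22e-07 to 0.0521. The collagen IV gene Col4a1, Gata4 and Sox17 did not pass, at 0.18 ± 0.08 (adjusted p = 0.0785), -0.29 ± 0.13 (adjusted p = 0.0595) and -0.15 ± 0.08 (adjusted p = 0.139). Without untreated replicate 3, Col4a1 (adjusted p = 0.0340) and Gata4 (adjusted p = 0.00708) passed, as did Gata4 without BMP4 replicate 1 (adjusted p = 0.0278) and Sox17 without BMP4 replicate 3 (adjusted p = 0.0343). Over all alternatives their adjusted p ran from 0.0340 to 0.705, 0.00708 to 0.277 and 0.0231 to 0.443.

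Afp itself was 6.02 ± 0.11 after BMP4 and 5.50 ± 0.42 (SD) untreated, where 1 of 3 arrays detected it. Its difference of 0.52 ± 0.17 passed (adjusted p = 0.0151) with overlapping arrays, and the call was lost without untreated replicate 3 (adjusted p = 0.0767, difference 0.33) or BMP4 replicate 2 (adjusted p = 0.0553), in a range of 0.000322 to 0.0767 over all alternatives.

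Of 13 measured BMP and SMAD target genes, 8 rose and 2 fell, as also adjusted over the list alone, and the list missed the threshold (adjusted p = 0.0673, 0.0373 to 0.306 over its alternatives). The list passed without untreated replicate 2 (adjusted p = 0.0476), with scale normalization (adjusted p = 0.0373) and with no background correction (adjusted p = 0.0495). Id3 rose by 2.16 ± 0.14, the intestinal and trophoblast transcription factor gene Cdx2 was at least 5.06-fold higher and the hepcidin gene Hamp at least 3.08-fold higher. Id2 rose by 0.56 ± 0.11, although its 3 probes ran from -0.26 to 0.88. The 2 that fell were Gata3, at least 4.38-fold lower, and Bmper. Of 14 BMP pathway components, 8 rose and 3 fell, or 9 and 3 adjusted over the list alone (adjusted p = 0.351). The BMP antagonist gene Chrd was at least 1.73-fold higher and the effector gene Smad1 rose by 0.60 ± 0.12, while the 3 that fell were Bmp8a, detected on 1 BMP4 array and at least 2.44-fold lower, Tob1 and Acvr1.

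Epithelial junction and keratin genes were higher after BMP4: 12 of 20 rose and 4 fell, as also adjusted over the list alone (adjusted p = 0.0164 for the list, adjusted p = 0.25 with an estimated correlation). Desmoglein 2 (Dsg2) rose by 2.93 ± 0.09, claudin 6 (Cldn6) by 2.76 ± 0.08 and occludin (Ocln) by 2.13 ± 0.11, but the 3 probes of Dsg2 ran from 0.07 to 2.93. Pkp2, Pard6b and Ctnna1 were among the 4 that fell. Of 21 mesenchymal and migration genes, 10 rose and 6 fell, as also adjusted over the list alone, and the list did not pass (adjusted p = 0.269). The receptor kinase gene Axl rose by 3.11 ± 0.11 and galectin 1 (Lgals1) by 2.47 ± 0.13, while the E-cadherin repressor gene Zeb1 fell by 2.26.

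Growth and metabolism genes also moved with BMP4. Of 34 cell cycle genes, 30 rose and 1, Mybl2, fell, as also adjusted over the list alone (adjusted p = 2.92e-08 for the list, adjusted p = 0.0694 with an estimated correlation). The mitotic kinase gene Aurkb rose by 1.10 ± 0.07, Bub1b by 1.04 ± 0.09, Cdc20 by 1.03 ± 0.07 and the replication gene Mcm7 by 0.90 ± 0.08. Of 20 glycolysis and hypoxia genes, 15 rose and 4 fell, as also adjusted over the list alone (adjusted p = 0.000421, adjusted p = 0.0694 with an estimated correlation), led by the glucose transporter genes Slc2a1 (1.41 ± 0.09) and Slc2a3 (1.19 ± 0.10) and by Vegfa (1.20 ± 0.11). The 4 that fell were Ndrg1 (-1.30 ± 0.11), Hk1, Egln3 and P4ha1. Of 22 cholesterol synthesis genes, 16 rose and 3 fell, as also adjusted over the list alone (adjusted p = 0.00819, adjusted p = 0.288 with an estimated correlation). Srebf2, a transcription factor gene of sterol synthesis, rose by 0.81 ± 0.08 and the reductase gene Dhcr7 by 0.79 ± 0.07, while Sc5d and Pmvk were among the 3 that fell. Of 9 imprinted and placental growth genes, 6 rose and 2, Snrpn and Impact, fell, as also adjusted over the list alone (adjusted p = 0.00855, adjusted p = 0.235 with an estimated correlation). The fetal growth factor gene Igf2 rose by 2.81 ± 0.07, H19 by 2.60 ± 0.11 and Phlda2 was at least 4.01-fold higher.

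Of 18 p53 target genes, 3 rose and 10 fell after BMP4, as also adjusted over the list alone, and the list was lower (adjusted p = 0.0368, adjusted p = 0.237 with an estimated correlation). That call was lost without untreated replicate 1 (adjusted p = 0.0521) or BMP4 replicate 3 (adjusted p = 0.0631), in a range of 0.00246 to 0.237. Plk2 fell by 1.74 and Sesn1 by 1.35, and the 3 that rose were Plk3 (1.04 ± 0.12), Gtse1 and Bbc3. Of 24 endocytosis and lysosome genes, 6 rose and 15 fell, or 6 and 16 adjusted over the list alone, and the list missed the threshold (adjusted p = 0.0673, 0.0292 to 0.303 over its alternatives). It passed with no background correction (adjusted p = 0.0495) and with no detection filter (adjusted p = 0.0292). The cell surface genes Amn, Lrp2 and Cubn were among the 6 that rose, while the lysosomal gene Psap fell by 1.20.

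The remaining lists did not pass with BMP4. Of 22 immediate early and dissociation stress genes, 10 rose and 4 fell (adjusted p = 0.225), with Hspb1 up by 2.11 ± 0.11 and Hspa1a at least 2.20-fold lower. Of 9 interferon and antigen presentation genes, 4 rose and 3 fell (adjusted p = 0.515), and the median of their changes was -0.06 while the mean was 0.57 and the test pointed up, with Ifitm1 the largest. Of 12 WNT and FGF pathway genes, 3 rose and 6 fell (adjusted p = 0.249), with Fgf10 down by 1.75, the WNT target Axin2 by 1.02 and Wnt11 at least 1.87-fold higher. Among markers of other cell types, 3 of 4 trophoblast genes rose (Cdx2, Plac1, Id2) and Gata3 fell (adjusted p = 0.168), and Flt1 rose while 4 other mesoderm, blood or endothelium genes fell (Cdh5, Runx1, Tek, Myl7, adjusted p = 0.0804). That list passed with no detection filter (adjusted p = 0.0374, 0.0374 to 0.235 over its alternatives). Of 5 definitive gut endoderm genes, 3 rose, Cdx2 and Cpm among them, and Foxa2 fell (adjusted p = 0.164). Of 5 pluripotency genes, Tbx3 rose and Klf2 and Dppa5a fell (adjusted p = 0.843). None of 3 fibroblast genes passed (adjusted p = 0.914), and 0 neural genes were measured. For these 8 tested lists the counts adjusted over the list alone were the same. Dppa5a, detected on 1 BMP4 array, was at least 1.17-fold lower. Without BMP4 replicate 1 its fitted difference, which uses values under the lowest detected signal, moved from -0.49 to -0.25. Dppa5a no longer passed without untreated replicate 1 (adjusted p = 0.0557) or untreated replicate 2 (adjusted p = 0.0532), in a range of 0.00781 to 0.0557.

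**Figure D1:**
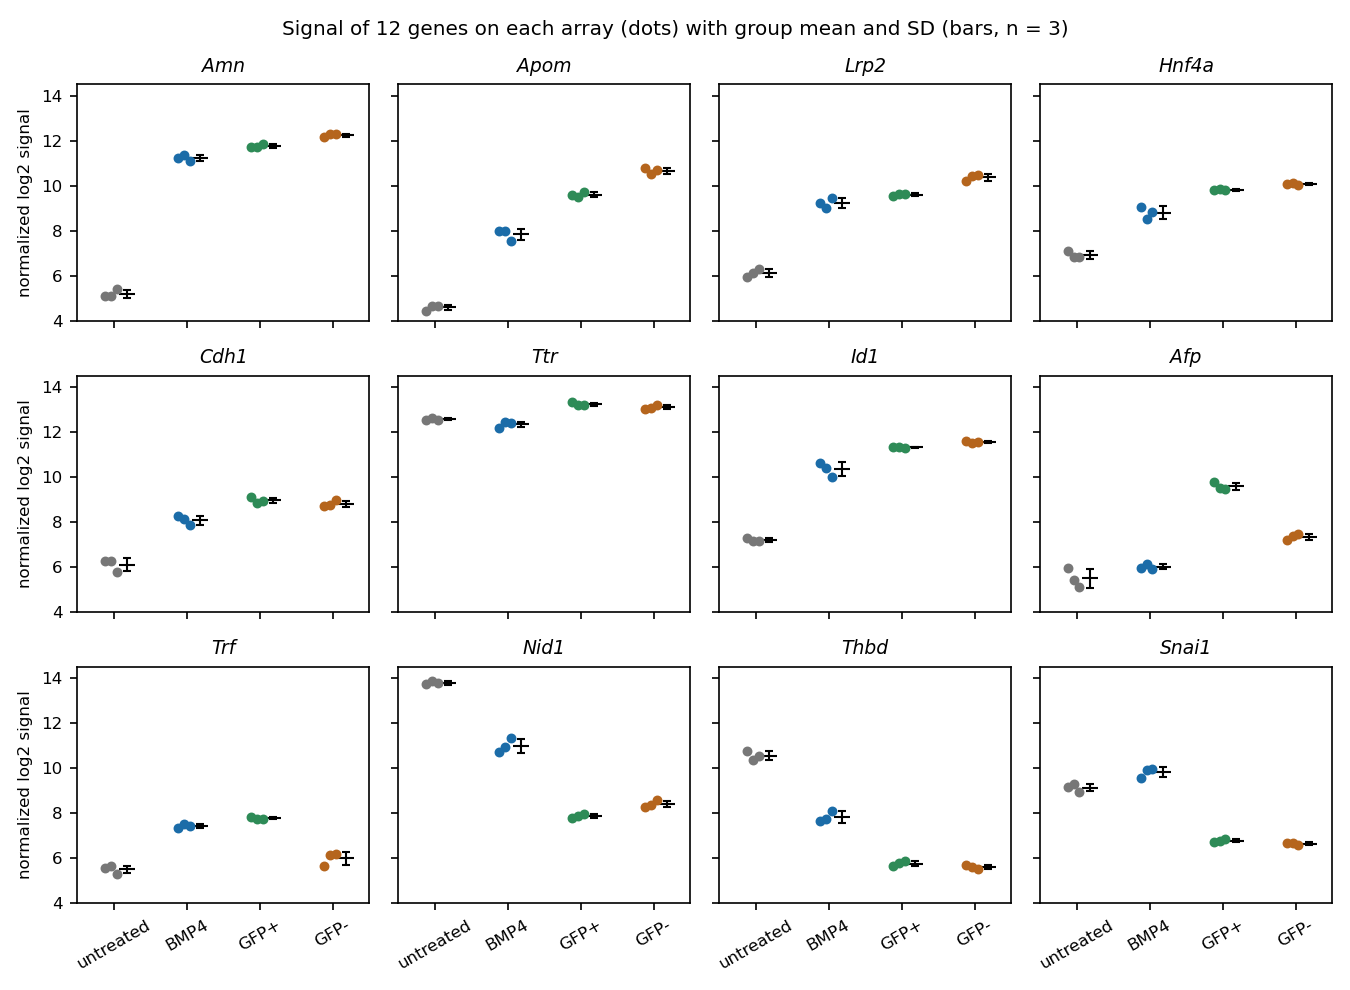
Normalized log2 signal of 12 genes (vertical axis) on each of the 12 arrays by group (horizontal axis), with dots for arrays and black bars for the mean and SD of 3 arrays. Amn lies at 5.21 in untreated cells and at 11.24 after BMP4, and Nid1 falls from 13.79 to 10.99. Afp is 9.58 in GFP positive and 7.35 in GFP negative cells, and 5.94 to 6.15 on unsorted BMP4 arrays.

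The second comparison asked how the GFP positive and GFP negative cells from BMP4-treated cultures differed. Afp (probe 5820315), which drives the reporter, was 9.58 ± 0.17 in GFP positive and 7.35 ± 0.13 (SD) in GFP negative cells, a difference of 2.23 ± 0.17 that checks the labels and is not a finding. The 1 probe for the reporter itself, EGFP, was not detected on any array, with a lowest detection p of 0.0406 in GFP positive and 0.0256 in GFP negative cells, so it does not check them. Genes of 3 secreted proteins were among the largest rises in GFP positive cells, although the serum protein list did not pass (adjusted p = 0.0598, 0.00597 to 0.377 over its alternatives): Spp2 (probe 4860068), a secreted phosphoprotein, by 1.81 ± 0.10 or 3.51-fold (adjusted p = 3.57e-07), transferrin (Trf) by 1.76 ± 0.13, and vitronectin (Vtn), not detected in GFP negative cells, at least 2.15-fold. Genes of the mesenchymal list were higher too, with Lgals1 up by 1.30 ± 0.13 and the smooth muscle actin gene Acta2 by 1.00 ± 0.12. The endocytic receptor genes Lrp2 and Cubn were lower by -0.77 ± 0.12 and -0.77 ± 0.10, and Apom by -1.06 ± 0.12 (adjusted p = 0.000174).

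Between the sorted cells 571 of 10597 genes differed, 5.39%, of which 325 were higher and 246 lower in GFP positive cells, and 40 differed at least 2-fold (27 higher, 13 lower). Without an adjustment 1966 genes had p under 0.05, and the arrays did not overlap in 27.4% of genes, against 10% by chance. Arrays moved that count: it was 289 without GFP positive replicate 1, 356 without GFP positive replicate 2, 306 without GFP negative replicate 2 and 353 without GFP negative replicate 3. It was 287 with scale normalization, where 139 were higher and 148 lower, and 918 with array weights. Among the 12 largest rises were also Ccdc80 and the annexin gene Anxa1, at least 2.38-fold and 2.14-fold higher and not detected in GFP negative cells, the keratin gene Krt20 (1.38 ± 0.20), the procollagen processing gene Pcolce (1.36 ± 0.15), Mucl3 (1.32 ± 0.14), the glutathione transferase gene Gsta3 (1.31 ± 0.10) and Cdkn1c (1.31 ± 0.12). Acss1, also not detected in GFP negative cells, was at least 1.38-fold higher.

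The kinase gene Tnk1 (probe 5490301) was 4.81 ± 0.06 in GFP positive cells, where no array detected it, and 6.50 ± 0.08 (SD) in GFP negative cells, at least 1.72-fold lower (adjusted p = 3.57e-07). Pdlim4, the amino acid transporter gene Slc7a8, the imprinted gene Phlda2, the BMP-binding protein gene Bmper and Arhgdig were likewise not detected in GFP positive cells and at least 1.57-fold, 1.91-fold, 2.15-fold, 1.41-fold and 1.22-fold lower. The adenosine receptor gene Adora2b differed by -1.54 ± 0.19, Rgl1 by -1.16 ± 0.09, the immediate early gene Egr1 by -1.08 ± 0.19 and Rcan2 by -1.05 ± 0.14. Rbp4 passed too (adjusted p = 0.000186), but no GFP positive array and 1 of 3 GFP negative arrays detected it, so no fold is given.

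Of 21 mesenchymal and migration genes, 6 were higher in GFP positive cells and 0 lower, or 11 and 0 adjusted over the list alone. The list was higher (adjusted p = 6.48e-08), and its call held with an estimated correlation (adjusted p = 0.0234 with an estimated correlation), which no other list did. Besides Lgals1 and Acta2, the calcium-binding protein gene S100a6 was higher by 1.24 ± 0.13 and Axl by 0.62 ± 0.11, and the other members past the threshold were fibronectin (Fn1) and Timp1. Vimentin (Vim) and Snai1 differed by 0.22 ± 0.07 (adjusted p = 0.0811) and 0.14 ± 0.11 (adjusted p = 0.557). Of 3 measured fibroblast genes, 2 were higher, as also adjusted over the list alone (adjusted p = 0.000745, adjusted p = 0.0875 with an estimated correlation, 0.198 with no detection filter). They were the collagen V gene Col5a1 (1.25 ± 0.14) and the collagen crosslinking enzyme gene Loxl1 (0.74 ± 0.15). Loxl1 no longer passed without GFP positive replicate 1 (adjusted p = 0.0634, range 0.00114 to 0.0634). The collagen I gene Col1a1, abundant in fibroblasts, was not detected on any array.

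Visceral endoderm markers split between the fractions: 5 of 24 were higher and 10 lower in GFP positive cells, or 5 and 11 adjusted over the list alone. The 5 that were higher were Trf, Apob (at least 1.81-fold, detected on 1 GFP negative array), Foxa1, Selenop and Apoa1 (0.61 ± 0.11), and the lower ones included Lrp2, Cubn, Amn (-0.49 ± 0.10), Apom and Apoe. Hnf4a, Ihh and Ttr differed by -0.27 ± 0.12, 0.17 ± 0.09 and 0.13 ± 0.08, with adjusted p = 0.253, 0.378 and 0.428. The list was lower (adjusted p = 0.0318, adjusted p = 0.344 with an estimated correlation). The call was lost without GFP positive replicate 3 (adjusted p = 0.0828), without GFP negative replicate 3 (adjusted p = 0.0622) and with the mean of the kept probes (adjusted p = 0.0640), in a range of 0.00587 to 0.344. Amn no longer passed without GFP positive replicate 1 (adjusted p = 0.0507, range 0.000488 to 0.0507). Of 12 serum proteins and coagulation factors, 5 were higher and 3 lower, or 6 and 3 adjusted over the list alone (adjusted p = 0.0598). The heme carrier hemopexin (Hpx) was higher by 1.12 ± 0.12, as were Trf, Kng1, Fga and Ambp, while coagulation factor X (F10) was lower by -0.97 ± 0.10, with Amn and Rbp4. That list passed without GFP negative replicate 2 (adjusted p = 0.0371), without GFP negative replicate 3 (adjusted p = 0.0321) and under 6 other settings, with an adjusted p as low as 0.00597 and as high as 0.377. Of 9 apolipoprotein and lipid transport genes, 4 were higher and 3 lower, as also adjusted over the list alone (adjusted p = 0.310). Vldlr (0.76 ± 0.07), Apob, Apoa1 and Apoa2 were higher, and Apom, Mttp (-0.62 ± 0.12) and Apoe lower.

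Cholesterol synthesis genes were lower in GFP positive cells (adjusted p = 9.96e-06, adjusted p = 0.210 with an estimated correlation): 3 of 22 were lower and 0 higher, or 6 and 0 adjusted over the list alone. Idi1 was lower by -0.70 ± 0.12, Dhcr7 by -0.37 ± 0.07 and Cyp51 by -0.37 ± 0.09. Of 24 endocytosis and lysosome genes, 5 were lower and 0 higher, or 8 and 1 adjusted over the list alone (adjusted p = 0.0363, adjusted p = 0.377 with an estimated correlation). The 5 were Lrp2, Cubn, Amn, Dab2 and the protease gene Lgmn (-0.43 ± 0.08). That call was lost without GFP positive replicate 3 (adjusted p = 0.0638), without GFP negative replicate 3 (adjusted p = 0.176), with the mean of the kept probes (adjusted p = 0.0946) and with only the compared groups in the fit (adjusted p = 0.0502), in a range of 0.00230 to 0.377. Of 11 primitive endoderm genes, 2 were lower, Sox7 (-0.46 ± 0.08, probes from -0.46 to -0.10) and Dab2 (-0.28 ± 0.07, probes from -0.31 to -0.07), as also adjusted over the list alone (adjusted p = 0.00488, adjusted p = 0.0875 with an estimated correlation). Gata6, Gata4 and Sox17 differed by -0.05 ± 0.10, -0.33 ± 0.13 and -0.14 ± 0.08, with adjusted p = 0.857, 0.173 and 0.422. Dab2 no longer passed without any 1 of the 6 arrays but GFP positive replicate 2, with adjusted p between 0.0533 and 0.141.

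Of 12 WNT and FGF pathway genes, 2 were lower in GFP positive cells, as also adjusted over the list alone (adjusted p = 0.0239, adjusted p = 0.111 with an estimated correlation). They were the FGF-responsive genes Etv5 (at least 1.31-fold, detected on 1 GFP positive array) and Dusp6, and Dusp6 was not detected in either fraction, so no fold is given. Of 9 imprinted and placental growth genes, Cdkn1c and H19 were higher and Phlda2 lower, or 5 and 1 adjusted over the list alone (adjusted p = 0.0252, adjusted p = 0.336 with an estimated correlation). The call was lost without GFP positive replicate 2 (adjusted p = 0.0517) or GFP negative replicate 1 (adjusted p = 0.0589), in a range of 0.0118 to 0.336. Of 34 cell cycle genes, 1, Tpx2, was lower, or 0 adjusted over the list alone, while the list as a set was lower (adjusted p = 0.0363, adjusted p = 0.377 with an estimated correlation). That call was lost without GFP positive replicate 1 (adjusted p = 0.0973), GFP positive replicate 2 (adjusted p = 0.0517) or GFP negative replicate 2 (adjusted p = 0.109) and with the mean of the kept probes (adjusted p = 0.0633), in a range of 0.00230 to 0.377.

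The other lists did not pass between the fractions. Of 13 BMP and SMAD target genes, Hamp was higher and Bmper, Id2 (-0.58 ± 0.11) and Hey1 were lower (adjusted p = 0.0675), and the list passed without GFP positive replicate 3 (adjusted p = 0.0243), without GFP negative replicate 3 (adjusted p = 0.0321) and under 3 other settings, with an adjusted p between 0.0243 and 0.785 over its alternatives. Id1 and Id3 differed by -0.24 ± 0.12 (adjusted p = 0.299) and -0.18 ± 0.14 (adjusted p = 0.520). None of 14 BMP pathway components (adjusted p = 0.435), 18 p53 target genes (adjusted p = 0.972) or 5 gut endoderm genes (adjusted p = 0.310) passed. Of 22 basement membrane genes, Lamb3 (1.06 ± 0.14) and Fbln2 (0.75 ± 0.09) were higher and Smoc1 (-0.54 ± 0.07), Nid1 and P4ha1 lower (adjusted p = 0.972). Of 3 anterior visceral endoderm markers, Fzd5 was higher by 0.68 ± 0.09 and Hhex lower by -0.49 ± 0.07 (adjusted p = 0.765). In these lists the counts adjusted over the list alone were the same.

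Of 19 parietal endoderm markers, Krt19 (0.50 ± 0.08) and Stra6 were higher and Nid1 lower, or 3 and 1 adjusted over the list alone (adjusted p = 0.387), and Krt19 was also the 1 of 20 epithelial genes that passed, as also adjusted over the list alone (adjusted p = 0.931). Of 22 stress genes, Dusp1 and Gadd45g were higher and Egr1 lower, or 3 and 1 adjusted over the list alone (adjusted p = 0.355). Of 20 glycolysis genes, Hk2 and P4ha1 were lower, or 4 adjusted over the list alone (adjusted p = 0.310). Of 9 interferon genes Ifitm1 was higher, or 2 adjusted over the list alone (adjusted p = 0.652). Among other cell types, Klf2 of 5 pluripotency genes was higher (adjusted p = 0.407), Id2 of 4 trophoblast genes lower (adjusted p = 0.0975) and the angiopoietin receptor gene Tek of 5 mesoderm, blood or endothelium genes higher (0.52 ± 0.07, adjusted p = 0.310 for the list). Adjusted over the list alone these numbers were the same, except 2 higher and 1 lower in the last. The trophoblast list passed without GFP negative replicate 3 (adjusted p = 0.0204, 0.0204 to 0.827 over its alternatives). The median, mean and test differed in sign for the anterior, parietal, epithelial, basement membrane, p53 and interferon lists, where the medians lay between -0.15 and -0.01.

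Calls of some list members between the fractions rested on single arrays. With all arrays kept, scale normalization ended the calls of 8 named genes between the fractions, and no detection filter also of 8. The ranges that follow cover only the left-out arrays. Leaving out any 1 of the 6 arrays ended those of Tpx2, Stra6 and Dusp1, with adjusted p of 0.0632 to 0.191, 0.0564 to 0.144 and 0.0669 to 0.124. Any 1 but GFP positive replicate 3 ended that of Hey1 (0.0853 to 0.179), any but GFP positive replicate 1 that of Hamp (0.0659 to 0.128) and any but GFP negative replicate 1 that of Nid1 (0.0527 to 0.129). Cyp51 (0.0706 to 0.156) and P4ha1 (0.0921 to 0.159) were lost without GFP positive replicates 1 or 3 or GFP negative replicates 2 or 3. Gadd45g (0.0676 to 0.0827) and Hk2 (0.0524 to 0.0554) were lost without GFP positive replicates 1 or 2 or GFP negative replicate 2, and Gadd45g also without GFP negative replicate 3. H19 (0.0502 to 0.0696) was lost without GFP positive replicates 1 or 2 or GFP negative replicate 1, Ifitm1 (0.0527 to 0.0638) without GFP positive replicate 1 or GFP negative replicates 2 or 3, and Klf2 (0.0515 to 0.0703) without GFP positive replicates 1 or 3 or GFP negative replicate 3.

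**Figure D2:**
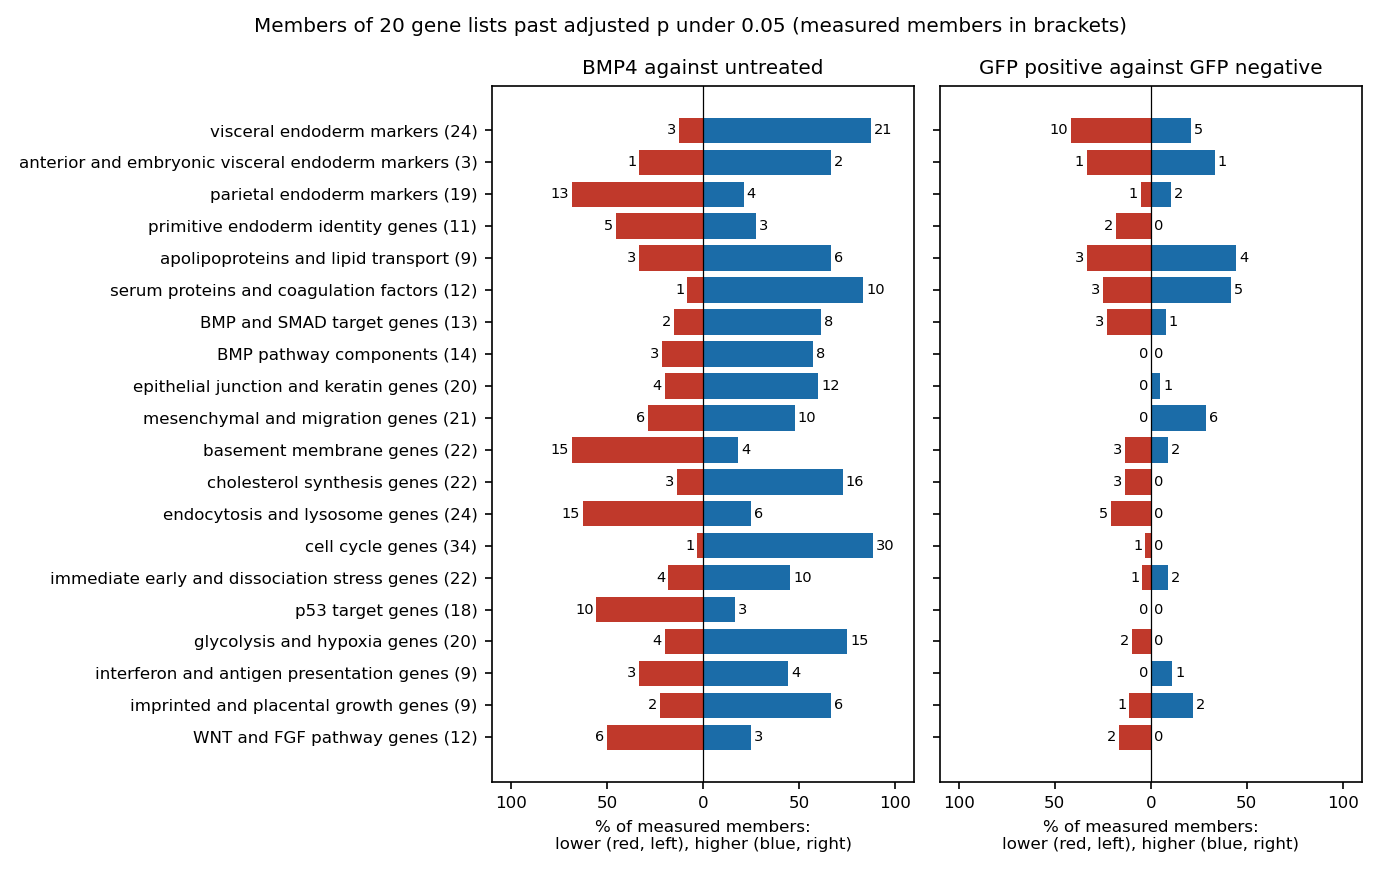
Percent of the measured members (horizontal axis) of 20 gene lists (vertical axis, measured members in brackets) that were lower, in red to the left, or higher, in blue to the right, at an adjusted p under 0.05, with numbers of genes at the bars. Visceral endoderm markers show 21 higher and 3 lower members after BMP4 but 5 higher and 10 lower in GFP positive cells.

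Genes that both comparisons called were set side by side. Of the 571 genes that differed between the fractions, 215 also changed with BMP4 in the same direction and 229 in the opposite one. With scale normalization these were 125 and 94, so neither direction held the majority throughout. All 4 combinations exceeded the number that independent lists would share: 124 against 98.2 for higher in both, 91 against 70.6 for lower in both, 137 against 93.3 for lower with BMP4 and higher in GFP positive cells, and 92 against 74.4 for the reverse. Both comparisons use the same estimate of spread for a gene, so a gene with little spread is more readily called in both. The calls are thus not independent, and the excess does not show that the comparisons are linked. Lrp2, Cubn, Apom and Tnk1 rose with BMP4 and were lower in GFP positive than in GFP negative cells. Lrp2, Cubn and Apom still lay higher on GFP positive than on unsorted BMP4 arrays, and Tnk1 lay lower. GFP negative arrays differed from the unsorted ones in the same direction for each of these genes. Sorting cannot be told apart from a difference between the sets of arrays here. Acss1 and Igfbp5 fell with BMP4 and were higher in GFP positive cells. Trf and Cdkn1c were higher in both, although on GFP positive arrays Cdkn1c lay under and Trf over the level of the unsorted BMP4 arrays. Across all genes the changes in the 2 comparisons had r = -0.04 and rho = -0.07, where genes are not independent replicates. The test of the signed difference, the log2 change between the fractions minus that with BMP4, called 5074 genes, 2478 positive and 2596 negative. A positive value also arises where BMP4 lowered a gene that did not differ between the fractions, so it does not mean a larger change there. The number of genes with opposite directions was 112 without GFP positive replicate 1, 135 without GFP positive replicate 2, 120 without GFP negative replicate 2 and 131 without GFP negative replicate 3. The number with the same direction was 124 without GFP positive replicate 1 and 131 without GFP negative replicate 2.

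**Figure D3:**
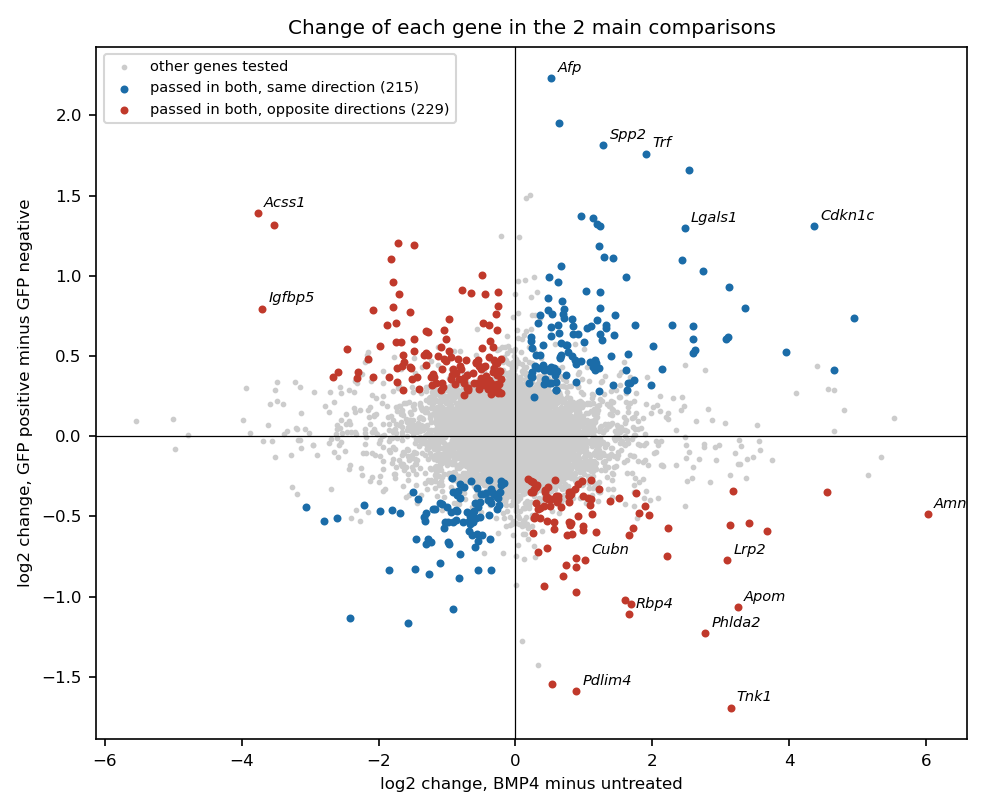
Log2 change of each of 10597 genes with BMP4 (horizontal axis) against the log2 difference between GFP positive and GFP negative cells (vertical axis), 1 dot per gene. The 215 genes that passed in both comparisons in the same direction are blue and the 229 with opposite directions red, with Lrp2 at 3.09 and -0.77.

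The third comparison set GFP negative cells against untreated cells, to ask whether the cells without reporter signal differed from cells never given BMP4. Amn was 12.26 ± 0.07 in GFP negative and 5.21 ± 0.18 (SD) in untreated cells, at least 109.8-fold (adjusted p = 6.64e-15), and the drug-metabolizing enzyme gene Fmo1 was at least 79.5-fold higher, each detected on 1 untreated array. Igf2 differed by 6.11 ± 0.07 and Plac8 by 5.29 ± 0.09, and Apom and Fbln1, not detected in untreated cells, were at least 36.8-fold and 48.9-fold higher. Nupr1, Depp1 and Mllt3 were not detected in GFP negative cells and were at least 82.9-fold, 24.6-fold and 16.3-fold lower, the water channel gene Aqp8 differed by -5.89 ± 0.18, Nid1 by -5.39 ± 0.13 and Tspan8 by -5.37 ± 0.15. Other probes gave less: as little as 1.89 for Fbln1, 2.28 for Fmo1, -1.97 for Mllt3 and -2.07 for Nid1. Snai1 was 6.65 ± 0.06 in GFP negative cells against 9.13 ± 0.16 in untreated and 9.81 ± 0.22 (SD) in unsorted BMP4 cells. In all, 7911 genes differed, 4076 higher and 3835 lower, with 2229 at least 2-fold apart (1158 higher, 1071 lower) and no overlap of arrays in 77.6%, against 10% by chance. Scale normalization moved the median difference of all genes from 0.0189 to -0.0951 and the higher genes from 51.5% to 43.3% of those called. The 6 sorted arrays had a median signal of at most 32.4 and the 6 unsorted ones of at least 53.4, so sorting and any difference between the sets of arrays cannot be told apart from BMP4 in each gene and list of this comparison.

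In GFP negative cells 22 of 24 visceral endoderm markers were higher than in untreated cells and 1, Foxa2, was lower, as also adjusted over the list alone (adjusted p = 2.42e-08, adjusted p = 0.0747 with an estimated correlation). Of 19 parietal endoderm markers, Cited1 and Krt19 were higher and 16 lower (adjusted p = 0.000194, adjusted p = 0.104 with an estimated correlation). Higher lists were epithelial genes, 15 and 1 lower of 20 (adjusted p = 0.000194, adjusted p = 0.131 with an estimated correlation), serum proteins, 10 and 0 of 12 (adjusted p = 0.000875, adjusted p = 0.131 with an estimated correlation), glycolysis genes, 16 and 4 of 20 (adjusted p = 0.00426, adjusted p = 0.125 with an estimated correlation), cell cycle genes, 22 and 4 of 34 (adjusted p = 0.00650, adjusted p = 0.286 with an estimated correlation), and apolipoproteins, 6 and 2 of 9 (adjusted p = 0.0276, adjusted p = 0.134 with an estimated correlation). BMP and SMAD targets were higher, 11 and 2 of 13, with Bmper and Gata3 the lower ones (adjusted p = 0.0187, adjusted p = 0.134 with an estimated correlation), a call lost with no detection filter (adjusted p = 0.0748). Of 18 p53 target genes, 3 were higher and 12 lower (adjusted p = 0.0240, adjusted p = 0.191 with an estimated correlation). Adjusted over the list alone the numbers were the same, except 16 higher epithelial genes and 13 lower p53 targets.

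The other lists of the third comparison did not pass. The basement membrane list, with 6 of 22 genes higher and 15 lower, lay at the threshold (adjusted p = 0.0504, 0.0352 to 0.381 over its alternatives) and passed without untreated replicate 1 (adjusted p = 0.0352) and without GFP negative replicate 3 (adjusted p = 0.0425). Cholesterol synthesis genes, 12 higher and 6 lower of 22 (adjusted p = 0.0798), passed without GFP negative replicate 1 (adjusted p = 0.0481, 0.00712 to 0.484 over its alternatives). Both also passed under other settings, 5 for the first and 3 for the second. Higher and lower members were 12 and 8 of 21 mesenchymal genes (adjusted p = 0.439), 7 and 4 of 14 BMP pathway components (adjusted p = 0.272), 3 and 5 of 11 primitive endoderm genes (adjusted p = 0.293), 9 and 14 of 24 endocytosis genes (adjusted p = 0.293), 11 and 7 of 22 stress genes (adjusted p = 0.437), 2 and 7 of 9 interferon genes (adjusted p = 0.192), 6 and 3 of 9 imprinted genes (adjusted p = 0.119), 5 and 6 of 12 WNT and FGF genes (adjusted p = 0.639) and 1 and 2 of 3 anterior markers (adjusted p = 0.778). Among other cell types they were 3 and 0 of 3 fibroblast genes (Col5a1, Loxl1 and Twist1, adjusted p = 0.0936), 3 and 1 of 4 trophoblast genes (adjusted p = 0.293), 1 and 3 of 5 mesoderm, blood or endothelium genes (adjusted p = 0.370), 3 and 2 of 5 gut endoderm genes (adjusted p = 0.672) and 1 and 2 of 5 pluripotency genes (adjusted p = 0.817). Cdx2, which counts as higher in the trophoblast and gut lists, was not detected in either group and gets no fold. Adjusted over the list alone these numbers were the same, except 2 and 2 pluripotency genes. The median, mean and test differed in sign for the anterior, endocytosis, pluripotency and mesoderm lists.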

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

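Testing each kept probe on its own and all alternatives for genes called in both main comparisons were chosen only after the results were seen. No named gene or list was called in the other direction under any alternative run. Among all genes, the mean of the kept probes turned the sign of 5 called genes for BMP4, 66 in the third comparison and 4 for the difference, and the stricter detection filter that of 1 in the third. Scale normalization turned the majority of the called genes from 325 higher and 246 lower to 139 and 148 between the fractions and from 4076 and 3835 to 3214 and 4208 in the third comparison. Medians of some lists changed sign, such as that of the fibroblast list between the fractions (-0.01 to 0.87) and that of BMP targets with BMP4 (-0.04 to 0.85). Of the named genes, 111 of 122 for BMP4, 90 of 121 between the fractions and 12 of 12 in the third comparison kept the same call throughout, as did 11, 14 and 14 of 25 lists. Some of these that were never called changed sign, such as Cdx2 (-0.21 to 0.11) and Foxa2 (-0.07 to 0.03) and the apolipoprotein (-0.03 to 0.17) and epithelial lists (-0.08 to 0.01) between the fractions. The rest crossed the threshold: among named genes 20 weaker and 16 stronger outcomes for BMP4 and 88 and 31 between the fractions, and among lists 13 and 6, 22 and 14, and 10 and 11.

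A log2 change of at least 1 left 1058 genes for BMP4, 40 between the fractions, 2229 in the third comparison and 1173 for the difference, since it asks for more than the test. Between the fractions scale normalization gave 287, array weights 918 and an adjusted p under 0.01 gave 240, against 571. The cause of the first 2 was not tested. Of the 287 genes 281 were among the 571. The processed table gave 12239 probes in the third comparison, where it holds more features, and 9177, 853 and 7318 in the others. Each kept probe on its own gave 8747, 683, 11339 and 7006. With an estimated correlation 0, 1 and 0 lists passed in place of 11, 9 and 9. A replicate block gave 6189, 503, 7861 and 5003 genes and 11, 9 and 10 lists. Under it Dusp1, Hamp, Hey1 and Tpx2 were no longer called between the fractions, while Wnt11 there, Gata4 and Loxl1 with BMP4 and the basement membrane list in the third comparison were. Arrays share only a number: residuals of equal numbers had r of -0.05, -0.04 and -0.01 for BMP4 and 0.15, 0.13 and -0.01 between the fractions, where arrays 1 and 2 but not 3 correlated best with their own number.

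Leaving out 1 array gave 5654 to 5979 genes for BMP4, 7512 to 7601 in the third comparison, 4653 to 5008 for the difference and 289 to 445 between the fractions: 289 without GFP positive replicate 1, 356 without GFP positive replicate 2, 306 without GFP negative replicate 2 and 353 without GFP negative replicate 3. Lists numbered 10 to 12, 7 to 10 and 9 to 10. Fewer arrays lower the power of each fit. Genes called in both main comparisons with opposite directions numbered 94 with scale normalization, 149 with no detection filter, 352 with array weights, 83 at an adjusted p under 0.01 and 11 at a log2 change of at least 1, against 229. Those with the same direction numbered 125, 144, 310, 101 and 15, against 215.

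The slide block was not run, since no slide is given, nor the processed table for lists and named genes, whose names could not be linked, nor the compared groups alone for the difference, which uses all 4 groups. Signal over background limits what the sorted arrays show of dim genes: their median signal was at most 32.4, and genes undetected in 1 group have only a bound for their fold.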

Other observations

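The tests of spread between arrays, of background over all bright genes, of a separate run, culture or sort, of unresponsive cells, of the dimmest array and of feeder fibroblasts were chosen only after the results were seen, as were the genes named here outside the naming rule. Several genes had a level in unsorted BMP4 cells that lay outside both fractions sorted from BMP4-treated cells. Snai1 was 9.81 ± 0.22 unsorted against 6.78 ± 0.07 in GFP positive and 6.65 ± 0.06 (SD) in GFP negative cells, n = 3 arrays each. H19 was 14.05 unsorted against 11.47 and 10.95, and Nid1 10.99 against 7.88 and 8.40. Igf2 was 11.32 unsorted against 14.79 and 14.62, and Cdx2 was detected only in unsorted BMP4 cells, at 7.82 ± 0.04. Afp, which drives the reporter, was 5.94 to 6.15 on the unsorted BMP4 arrays. It was 9.46 to 9.77 on GFP positive and 7.20 to 7.46 on GFP negative arrays, so both fractions lay above the unsorted cells.

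All 3 unsorted BMP4 arrays lay above or all below the 6 sorted arrays in 59.5% of genes (3125 above, 3185 below), where chance gives 2.38%, which argues against spread between arrays. A higher background on the unsorted arrays stays open: over all 1863 bright genes, with all 4 group means above 10, the median distance to the nearer fraction was 0.218 (quartiles 0.0871 to 0.411), between the under 0.1 that background predicted and the 0.25 set to exclude it. The 1141 bright genes picked for lying outside had a median of 0.358, against 0.522 for all genes outside, and 37 of them lay outside by at least 2-fold, against 962 of all. A separate array run, culture or sort handling cannot be told apart from sorting, since 0 groups had both sorted and unsorted arrays. Effects of sorting on the cells themselves were not tested and may add to the pattern.

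Lrp2, Cubn, Amn, Apom and Rbp4 rose with BMP4 and were lower in GFP positive than in GFP negative cells. Against unsorted BMP4 cells, Amn (11.77 against 11.24), Apom (9.61 against 7.85), Lrp2 and Cubn were higher in GFP positive cells, and Rbp4 was lower. GFP negative cells differed from unsorted cells in the same direction for all 5, and sorting cannot be told apart from a separate run or culture. Of 442 genes raised at least 2-fold by BMP4, 58 were higher and 31 lower in GFP positive cells. More unresponsive cells in the GFP positive fraction would alone make most raised genes lower, so they were not the only difference between the fractions. Of 616 genes lowered at least 2-fold, 58 were higher and 29 lower. Raised and lowered genes thus leaned the same way, as did all called genes (325 higher, 246 lower). The splits therefore do not decide whether such cells lowered the 5 genes. The dimmest array is argued against, since 5 of the 5 genes were called lower without GFP positive replicate 3. Rbp4 adds little to that: it was detected on 1 GFP negative array, with a mean of 5.65 under the lowest detected signal of 5.73. Without GFP positive replicate 1 the call of Amn was lost (adjusted p = 0.0507, range 0.000488 to 0.0507).

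Mesenchymal genes such as Lgals1 and fibroblast list genes such as Col5a1 were higher in GFP positive cells. Feeder fibroblasts carried into the sorted fraction are argued against, since 0 of Col1a1, Col1a2 and Col3a1, abundant in fibroblasts, were detected on any GFP positive array (lowest detection p 0.143, 0.301 and 0.274). That rests on the response of these probes, which no array here tested. A difference in state among the XEN cells themselves may remain, and was not tested.

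For single comparisons the 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05. The real split, 1 of 10 with a count as large, gave 6244, 571 and 7911 genes, and the highest other 0, 0 and 0. For lists it gave 11, 9 and 9, and the highest other 6, 3 and 8. For the difference between the GFP and BMP4 comparisons, 100 regroupings of both pairs at once (of 200 possible) were taken, the real one included. Only the real one gave as many as the 5074 genes. The highest other gave 4606, among the 12 that kept the BMP4 split, and the highest without that split 6. The count thus follows the split of the BMP4 and untreated arrays, which has only 10 forms. The regroupings therefore do not exclude chance for the BMP4 side or for the GFP side.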
